A study of Mus musculus with 4 samples.

How the data were processed

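RNA from primary mouse keratinocytes was measured on 4 single-channel Affymetrix MTA-1_0 arrays, 2 of wild-type cells and 2 of Glut1-deficient cells. Per the labels, the cells came from C57BL/6J mice of 1 week of age, 4 per genotype. They grew in a keratinocyte medium with 0.05 mM CaCl2, were reseeded after 3 days at 2000000 cells and were harvested the next day. Per the series' design text, each array held RNA from 2 plates of a genotype that were combined at random, so arrays with the same replicate number are not tied to a shared animal. The per-gene p-values measure the spread between these samples, part of which may be technical, and the number of arrays limits the precision.

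The deposited values are log2 signals per transcript cluster, made with Affymetrix Expression Console and RMA per the submitters' processing notes, and called gene-level SST-RMA signals per the labels. Software versions, the annotation release, which arrays were normalized together and any further filter are not given in the sources used here. RMA subtracts a modelled background, equalises the distributions of the arrays and summarises the probes of a gene. A deletion of part of a gene can therefore leave signal in its row, and a shift shared by most genes would be removed. SST-RMA also transforms the signal, and the values reached 19.7, so folds may differ from those of plain RMA. How far they do was not tested. The table held 72688 rows, of which 6732 were control rows. A platform table named 1 gene symbol for 30604 rows, several for 2146 rows and none for 33206 rows that are no control. Entrez identifiers of 22818 of the rows with 1 symbol matched a RefSeq gene table of GRCm38.p6, which updated 827 symbols and was used for names only.

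The 30604 rows with 1 symbol, covering 30142 genes, were compared between genotypes with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, without a replicate block. Tests were two-sided, and rows with a Benjamini-Hochberg adjusted p under 0.05 were called changed. All fold changes are Glut1-deficient minus wild type on the log2 scale, with the moderated standard error (SE). For 355 genes with more than 1 row, the row with the highest mean over the 4 arrays stood for the gene. In each array the 95th percentile of 23 background control rows served as a floor, between 4.36 and 4.87. Where both arrays of a group lay at or below it, a fold is given only as a bound against that floor ("at least").

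There were 34 gene lists, 27 of pathways or cell states and 7 of markers of other cell types that skin cultures can hold. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists. At this preset the camera p-values rest mainly on the spread over genes, so they do not measure the spread between samples. Estimated correlations ran from -0.127 to 0.735, with 0.478 for the amino acid response list and 0.671 for the G2 and M phase list. Older symbols in the lists were matched through RefSeq synonyms, which brought in 3 members. Of these, Serpina1c entered the alarmin list for Pi3, may be another gene than the one meant, and lay at background in both groups. Each list was also tested with an estimated correlation. A further test, fry, asks whether the genes of a set move one way on balance without comparing them with other genes. Camera with an estimated correlation uses the 2 residual degrees of freedom of the fit, so a list that fails it is not shown to be unchanged. The named genes are Slc2a1 and, among changed genes whose groups did not overlap, the 13 largest rises and 13 largest falls. They also include up to 4 members with the smallest p of each list that passed or had a member that passed (otherwise up to 2). The 3 most abundant members of each marker list complete them. Not all of these genes are printed below, but all enter the counts of named genes. Predicted, microRNA, small nucleolar and unnamed loci were left out of the largest changes. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined. Genes and alternatives chosen later are identified as such where they appear.

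The procedure was tested on simulated data with the real row means and 200 changed rows among 30604. For the comparison of 2 arrays with 2 it recovered 49.3% of 2-fold changes, 89.6% of 4-fold changes and 95.5% of 8-fold changes. Of its calls, 5.45% were unchanged rows. The simulation drew genes independently of each other. It called 0 of 30 unchanged lists and 2 of 2 changed lists. Its 200 changed rows were fewer than the 2209 rows called in the data. The share of changed rows sets the cutoff on p, so the recovery rates do not carry over directly. Variances came from the distribution that limma fitted, with normal noise, so the share of unchanged rows among the calls does not check the real arrays. The alternatives covered normalization, the rows tested, variance moderation, a replicate block, each array left out in turn, thresholds and the set test.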

Results

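Gene expression was compared between primary keratinocytes of wild-type mice and of mice lacking the glucose transporter Glut1 (gene Slc2a1) in keratinocytes, with 2 arrays per genotype. The array medians lay between 4.19 and 4.24 on the log2 scale. Pearson correlations across the named rows were 0.998 between the wild-type arrays, 0.997 between the Glut1-deficient arrays and 0.989 to 0.992 between genotypes. The first principal component held 74.0% of the variance and separated the genotypes.

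Slc2a1 signal was 13.26 and 13.40 on the wild-type arrays and 12.09 and 12.01 on the Glut1-deficient arrays. The gene fell by 1.28 on the log2 scale (SE 0.10, n = 2 per group, limma adjusted p = 0.00754). Its row summarises probes over the gene, and the deleted part is not given in the sources used here, so the remaining signal is no measure of remaining function. Without Glut1-deficient replicate 1 the change was -1.32 with an adjusted p of 0.0508, and with every row of the table in the test the adjusted p was 0.0648, in a range over all alternatives from 0.00545 to 0.0648.

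Beyond the target gene, the cells lacking Glut1 had higher transcripts of many amino acid response genes and lower transcripts of many cell division genes. B4galnt2, a glycosyltransferase, had the largest rise, from 4.55 ± 0.25 to 12.11 ± 0.17 (mean ± SD, n = 2 per group), with the wild-type level close to the background floor. Ppbp, a chemokine, had the largest fall, from 16.23 ± 0.19 to 10.57 ± 0.60. In all, 2209 of 30604 rows changed, 1257 higher and 952 lower, and 459 of the higher and 337 of the lower rows changed at least 2-fold. These rows named 2193 genes. Groups did not overlap in 15195 rows, or 49.7%, where chance gives 33.3%. The count fell to 389 without wild-type replicate 1, 566 without wild-type replicate 2, 314 without Glut1-deficient replicate 1 and 1214 without Glut1-deficient replicate 2. It was 74 when every row of the table, control rows included, was tested.

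**Figure D1:**
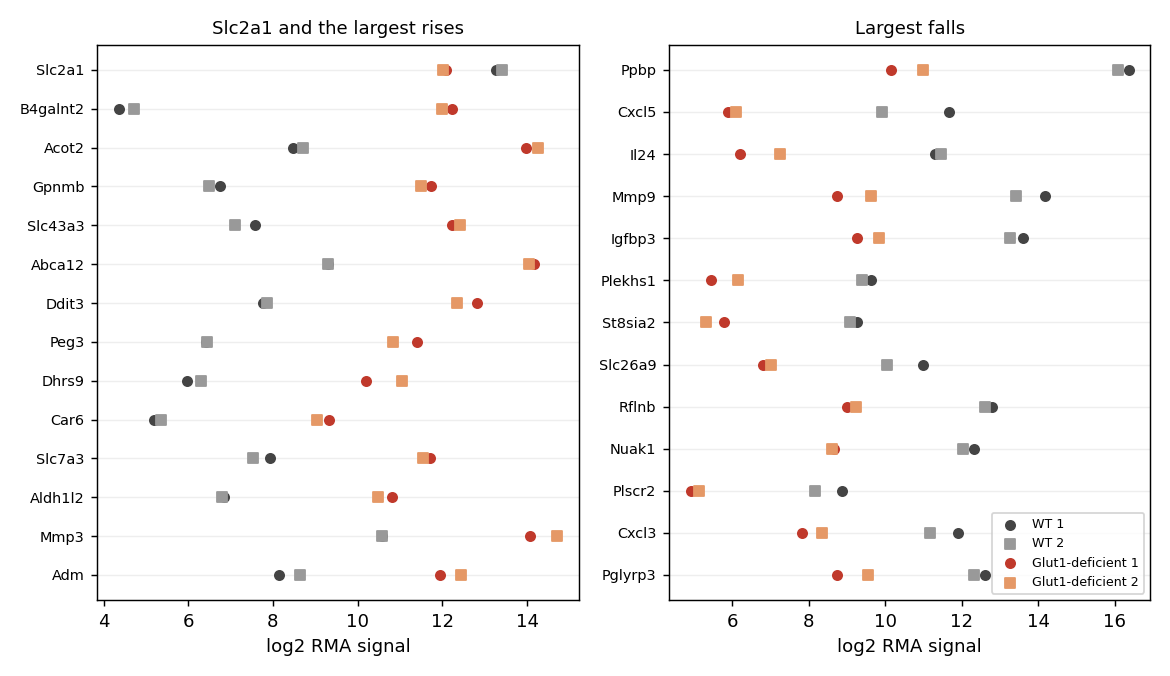
Log2 RMA signal on each of the 4 arrays (points, x axis) for Slc2a1, the 13 largest rises and the 13 largest falls (y axis). For each gene both Glut1-deficient arrays lie on one side of both wild-type arrays, as for B4galnt2 with means of 4.55 and 12.11.

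The 13 largest rises ranged from 3.81 to 7.57 on the log2 scale. Among them were Acot2, a mitochondrial acyl-CoA thioesterase (log2 fold change 5.52, SE 0.14), Gpnmb, a lysosome-associated glycoprotein (5.00, SE 0.14), and Abca12, the lipid transporter of lamellar granules (4.80, SE 0.10). The imprinted gene Peg3 rose by 4.69, the retinol dehydrogenase gene Dhrs9 by 4.49, the carbonic anhydrase gene Car6 by 3.90 and the mitochondrial folate enzyme gene Aldh1l2 by 3.83. The solute carrier genes Slc43a3 and Slc7a3 rose by 4.98 and 3.89, the matrix metalloproteinase gene Mmp3 by 3.82 and Adm, which encodes adrenomedullin, by 3.81. The 13 largest falls included Cxcl5 (-4.80, SE 0.55), the cytokine gene Il24 (-4.66, SE 0.34), the gelatinase gene Mmp9 (-4.60, SE 0.37) and Igfbp3 (-3.88, SE 0.22). Plekhs1, St8sia2, Slc26a9, Rflnb, Nuak1, Plscr2, Cxcl3 and Pglyrp3 fell by 3.71, 3.62, 3.61, 3.57, 3.54, 3.49, 3.44 and 3.32. Adjusted p-values of these 26 genes were at most 0.0154. Without Glut1-deficient replicate 1 the calls of Cxcl5, Slc26a9, Cxcl3 and Plscr2 were lost (adjusted p = 0.0918, 0.0650, 0.0562 and 0.0524), and that of Cxcl5 also without Glut1-deficient replicate 2 (0.0619). The fold of Cxcl5 depended on the wild-type arrays: its log2 fold change was -3.94 without replicate 1 and -5.67 without replicate 2.

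Genes of the amino acid response driven by Atf4 rose together: 28 of 34 measured members rose, none fell and 6 did not pass, with 32 higher when adjusted over the list alone. Ddit3, a transcription factor of the stress response, rose by 4.77 (SE 0.18) on its brighter row and 4.29 on its other row, the cationic amino acid transporter gene Slc7a3 by 3.89, Stc2 by 2.45 and Chac1, a glutathione-degrading enzyme, by 2.27. The list ranked above other genes (camera adjusted p = 2.14e-29; adjusted p = 0.462 with an estimated correlation). Between 14 and 26 members passed when 1 array was left out. In the unfolded protein response of the endoplasmic reticulum, 5 of 20 members rose, none fell and 15 did not pass (8 higher and 3 lower adjusted over the list alone). Sel1l rose by 1.20 and Derl3 by 1.74, and 1 to 3 members passed when 1 array was left out. Its camera adjusted p was 0.0129, against adjusted p = 0.481 with an estimated correlation, and it was 0.122 without Glut1-deficient replicate 2, 0.113 after quantile normalization and 0.0713 among rows at or above the median mean, in a range over the alternative fits from 0.00157 to 0.122. Derl3 was lost without wild-type replicate 1 or 2 (adjusted p = 0.0865 and 0.0742) and Sel1l without Glut1-deficient replicate 1 (0.0557).

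Autophagy and lysosome genes were higher in 8 of 26 members, with none lower and 18 not passing (15 higher and 2 lower adjusted over the list alone). Sqstm1, an autophagy receptor, rose by 1.81 (SE 0.11), Fnip1 and Fnip2, partners of folliculin, by 1.42 each, and the lysosomal channel gene Mcoln1 by 1.40. The camera adjusted p was 5.97e-08, with adjusted p = 0.462 with an estimated correlation. Markers of melanocytes also ranked higher, with a median log2 fold change of 0.46. Hypoxia-responsive genes rose in 5 of 19 members, with 14 not passing (10 higher and 1 lower adjusted over the list alone), including Vegfa (1.84), Ndrg1 (2.42) and Adm (3.81). Oxidative stress genes under Nrf2 rose in 7 and fell in 1 of 29 members, with 21 not passing. Adjusted over the list alone, 12 were higher and 2 lower. The rises included Hmox1 (1.98), Slc7a11 (1.86) and Gstm1 (1.39). Slc7a11 is also a member of the amino acid response list, so the 2 lists are not separate evidence for it. The hypoxia and Nrf2 lists had camera adjusted p-values of 0.000537 and 0.00175, against adjusted p = 0.599 with an estimated correlation and adjusted p = 0.601 with an estimated correlation. The Nrf2 call was lost without Glut1-deficient replicate 2 (adjusted p = 0.201, in a range over the alternative fits from 2.95e-06 to 0.201). Immediate early genes rose in 6 and fell in 1 of 19 members, with 12 not passing (11 higher and 2 lower adjusted over the list alone). Fos rose by 1.56, Btg1 by 1.11 and Jund by 1.05, while Ier3 fell by 1.03 (camera adjusted p = 6.91e-06; adjusted p = 0.462 with an estimated correlation). With 1 array left out 3 to 7 autophagy and lysosome genes, 3 to 5 hypoxia genes, 2 to 4 Nrf2 genes and 2 to 5 immediate early genes passed. Jund was lost without wild-type replicate 1 or 2 or Glut1-deficient replicate 1 (adjusted p = 0.124, 0.108 and 0.0739), Mcoln1 and Ier3 without wild-type replicate 1 (0.0501 and 0.0635) or Glut1-deficient replicate 1 (0.0527 and 0.0562), Hmox1 without wild-type replicate 1 (0.0559) and Btg1 without Glut1-deficient replicate 1 (0.0550).

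**Figure D2:**
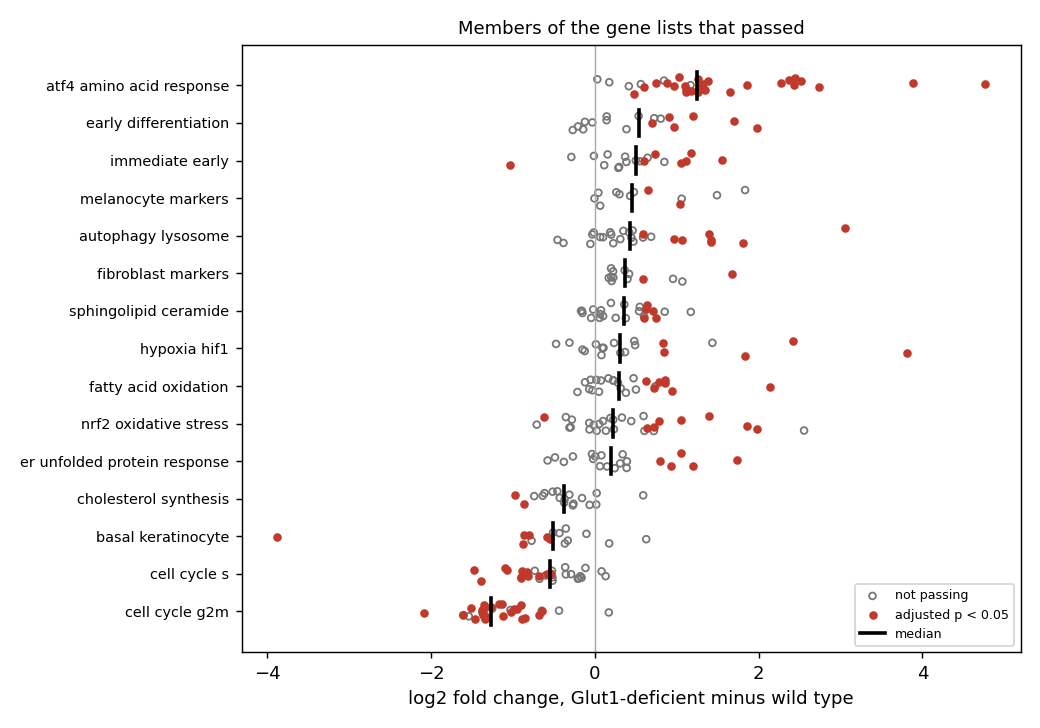
Log2 fold change (x axis, Glut1-deficient minus wild type) of each measured member of the 15 gene lists that passed (y axis); filled points passed over all genes, open points did not, and black bars are medians. The amino acid response list had the highest median, 1.25, and the G2 and M phase list the lowest, -1.26.

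Cell division genes were lower. Of the G2 and M phase genes 24 of 32 fell, none rose and 8 did not pass (30 lower adjusted over the list alone), and of the S phase genes 13 of 30 fell, none rose and 17 did not pass (21 lower adjusted over the list alone). The mitotic kinesin genes Kif20a and Kif4 fell by 1.60 (SE 0.14) and 1.51 (SE 0.13), the mitotic kinase gene Plk1 by 1.35 and Prc1 by 1.12. The ribonucleotide reductase genes Rrm2 and Rrm1 fell by 1.48 and 1.07, and the replication licensing gene Cdc6 by 1.39. The camera adjusted p was 1.45e-20 for G2 and M phase (adjusted p = 0.481 with an estimated correlation; fry adjusted p = 0.0612) and 2.62e-13 for S phase (adjusted p = 0.462 with an estimated correlation). With 1 array left out 3 to 23 G2 and M phase genes and 0 to 7 S phase genes passed, the fewest without Glut1-deficient replicate 1, where Rrm1, Cdc6, Rrm2 and Prc1 had adjusted p-values of 0.0701, 0.0722, 0.0524 and 0.0562. Plk1 and Prc1 were lost without wild-type replicate 1 (0.0525 and 0.0540), and Rrm1 and Prc1 without wild-type replicate 2 (0.0573 and 0.0531). Targets of p53 rose in 3 and fell in 1 of 20 members, with 16 not passing (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.265), with Trp53inp1 at 1.14 and Ccng1 at -0.66, the latter lost whichever of the 4 arrays was left out (adjusted p from 0.0533 to 0.143), and 1 to 3 members passed in those fits.

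Basal keratinocyte genes fell in 6 of 15 members, with none rising and 9 not passing (12 lower and 1 higher adjusted over the list alone). Igfbp3 fell by 3.88 (SE 0.22), and the hemidesmosome and adhesion genes Itga3, Col17a1 and Lamb3 fell by 0.87, 0.86 and 0.80 (camera adjusted p = 2.83e-06; adjusted p = 0.462 with an estimated correlation). Early differentiation genes rose in 6 of 17 members, with 11 not passing (10 higher adjusted over the list alone), such as Sbsn by 1.70 and the transcription factor genes Grhl1, Klf4 and Klf5 by 0.97, 0.91 and 0.70 (camera adjusted p = 0.000381; adjusted p = 0.462 with an estimated correlation). Cornified envelope and barrier genes went both ways: 7 of 43 rose, 5 fell and 31 did not pass (8 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.497). Abca12 rose by 4.80, the corneodesmosome gene Cdsn by 3.25 and the lipoxygenase gene Aloxe3 by 1.74, while the envelope precursor gene Sprr2b fell by 2.68. The cornified envelope list passed without wild-type replicate 2 (camera adjusted p = 0.0136, in a range over the alternative fits from 0.0136 to 0.894). With 1 array left out 1 to 2 basal, 0 to 4 early differentiation and 4 to 10 cornified envelope genes passed, and Col17a1, Lamb3, Grhl1 and Klf5 were lost whichever of the 4 arrays was left out (adjusted p from 0.0567 to 0.125). Itga3 and Klf4 were lost without either wild-type array or Glut1-deficient replicate 1 (adjusted p from 0.0607 to 0.101), and Sbsn without Glut1-deficient replicate 1 or 2 (0.134 and 0.102).

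Alarmin, cytokine and wound keratin genes rose in 3 and fell in 8 of 27 members, with 16 not passing (7 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.218; fry adjusted p = 0.0455). Cxcl5, Il24, Cxcl3 and Cxcl2 fell by 4.80, 4.66, 3.44 and 2.36, and Il1f9, an interleukin 36 gene, rose by 2.52 (SE 0.18). Genes of the TGF-beta response and of epithelial-mesenchymal transition rose in 5 and fell in 7 of 22 members, with 10 not passing (6 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.534). Thbs1 fell by 2.58 and Ccn1 by 1.26, while the metalloproteinase genes Mmp3 and Mmp10 rose by 3.82 and 1.71. Interferon response genes rose in 1 and fell in 2 of 28 members, with 25 not passing (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.482); Ddx58 and Ifih1, both RNA sensors, fell by 1.03 and 1.01. Ifih1 was lost without Glut1-deficient replicate 1 or 2 or wild-type replicate 1 (adjusted p = 0.172, 0.104 and 0.102), and Ddx58 without wild-type replicate 1 or 2 or Glut1-deficient replicate 1 (0.0674, 0.0638 and 0.0607). Cxcl5 was lost without Glut1-deficient replicate 1 or 2 and Cxcl3 without replicate 1 (0.0918, 0.0619 and 0.0562). Of the EGFR ligands and receptors 1 of 12 rose, none fell and 11 did not pass (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.919), namely the ligand gene Epgn by 2.98 (SE 0.27). Leaving out 1 array left 4 to 9 alarmin, 7 to 9 TGF-beta, 0 to 2 interferon and 1 EGFR genes passing.

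In lipid metabolism, fatty acid oxidation genes rose in 7 of 24 members with 17 not passing (9 higher adjusted over the list alone), led in size by Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane, at 2.14 (SE 0.27), with Eci2 at 0.95 and Hadh at 0.86. Sphingolipid and ceramide genes rose in 5 of 23 members with 18 not passing (11 higher adjusted over the list alone), including Kdsr by 0.75 and the ceramide synthase gene Cers2 by 0.72. Camera adjusted p-values were 1.28e-05 and 5.68e-05, against adjusted p = 0.525 with an estimated correlation and adjusted p = 0.462 with an estimated correlation. Cholesterol synthesis genes fell in 2 of 18 members, Pmvk by 0.97 and Hmgcs1 by 0.87, with 16 not passing (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 5.68e-05; adjusted p = 0.462 with an estimated correlation). Fatty acid synthesis genes rose in 2 and fell in 1 of 18 members with 15 not passing (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.598), with Elovl4 at 1.21 and Fads2 at -1.08. With 1 array left out 0 to 1 gene of the fatty acid oxidation, sphingolipid and cholesterol lists passed each, and 0 to 3 of fatty acid synthesis. Eci2, Hadh, Kdsr, Cers2 and Hmgcs1 were lost whichever of the 4 arrays was left out (adjusted p from 0.0503 to 0.138). Pmvk was lost without either wild-type array or Glut1-deficient replicate 1 (0.0655, 0.0512 and 0.0562), Cpt1a without wild-type replicate 1 (0.0668), Elovl4 without wild-type replicate 1 or Glut1-deficient replicate 1 (0.0750 and 0.0524) and Fads2 without the latter (0.0628).

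Among glucose-handling genes Txnip and Arrdc4, arrestin genes induced by the glucose sensors of the Mondo family, fell by 3.16 (SE 0.11) and 1.53 (SE 0.20), and Fgf21 rose at least 1.13-fold from background, which made 1 higher, 2 lower and 7 not passing of 10 targets (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.486; fry adjusted p = 0.0455). Glycolysis genes rose in 2 and fell in 1 of 19 members with 16 not passing (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.497). The lactate exporter gene Slc16a3 fell by 1.32, while Slc16a1 rose by 0.93 and Pfkfb3 by 0.68. Among 14 other hexose transporters 1 rose, Slc50a1 by 0.84, and 13 did not pass (1 higher adjusted over the list alone; camera adjusted p = 0.563). Pentose phosphate genes rose in 2 of 8 members with 6 not passing, Taldo1 by 0.78 and Pgls by 0.61 (2 higher adjusted over the list alone; camera adjusted p = 0.886). Hexosamine and glycosylation genes rose in 3 and fell in 1 of 18 members with 14 not passing (5 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.466), with Gnpnat1 and Ogt at 0.92 and 0.82 and the hyaluronan synthase gene Has2 at -0.85. Tricarboxylic acid cycle genes rose in 2 and fell in 1 of 22 members with 19 not passing (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0521, from 0.0103 to 0.217 over the alternative fits), with Idh2 at 1.33 and Pdk3 at -0.51. In oxidative phosphorylation 1 of 31 members rose, Sdhb by 0.65, and 30 did not pass (0 adjusted over the list alone; camera adjusted p = 0.224). Leaving out 1 array left 1 to 2 Mondo targets, 0 to 2 glycolysis and 0 to 2 hexosamine genes, 0 to 1 pentose phosphate gene, 1 tricarboxylic acid cycle gene and no hexose transporter or oxidative phosphorylation gene passing. Pdk3, Sdhb, Fgf21, Pfkfb3, Slc50a1, Ogt and Pgls were lost whichever of the 4 arrays was left out (adjusted p from 0.0529 to 0.225). Has2, Gnpnat1, Slc16a1 and Taldo1 were lost without either wild-type array or Glut1-deficient replicate 1 (0.0655 to 0.125), Arrdc4 without Glut1-deficient replicate 1 or 2 (0.0837 and 0.0717), and Idh2 and Slc16a3 without Glut1-deficient replicate 1 (0.0524 and 0.0562).

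Of the markers of other skin cell types, 8 of 10 endothelial, 15 of 17 leukocyte and 9 of 11 muscle and adipocyte genes lay at background in both groups. Melanocyte markers ranked higher in Glut1-deficient arrays, with 2 of 12 rising and 10 not passing (7 higher adjusted over the list alone; camera adjusted p = 0.000257; adjusted p = 0.599 with an estimated correlation). Pmel rose by 1.04. Tyrp1 was 10.25 and 9.67 on the wild-type arrays against 12.11 and 10.80 (adjusted p = 0.136), and Dct had a log2 fold change of 1.84 (adjusted p = 0.0670). Both passed without Glut1-deficient replicate 2 (adjusted p = 0.0477 for Tyrp1 and 0.0378 for Dct), where their log2 fold changes were 2.15 and 2.43, against 0.83 and 1.24 without replicate 1. Fibroblast markers also ranked higher, with 2 of 13 rising and 11 not passing (5 higher adjusted over the list alone; camera adjusted p = 6.99e-06; adjusted p = 0.462 with an estimated correlation), and 5 of the 13 lay at background in both groups. Dcn rose at least 2.14-fold from background and Col6a1 by 0.59 on the log2 scale, while Postn and Col1a1 had log2 fold changes of 0.96 and 0.22 that did not pass, that of Postn being 1.56 without Glut1-deficient replicate 1 and 0.35 without replicate 2. With 1 array left out 0 to 4 melanocyte and 0 to 1 fibroblast markers passed. Col6a1 was lost whichever of the 4 arrays was left out (adjusted p from 0.0883 to 0.191), Pmel without wild-type replicate 1 or 2 or Glut1-deficient replicate 1 (0.0903, 0.122 and 0.0962) and Dcn without wild-type replicate 1 or 2 (0.0697 and 0.0834).

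**Figure D3:**
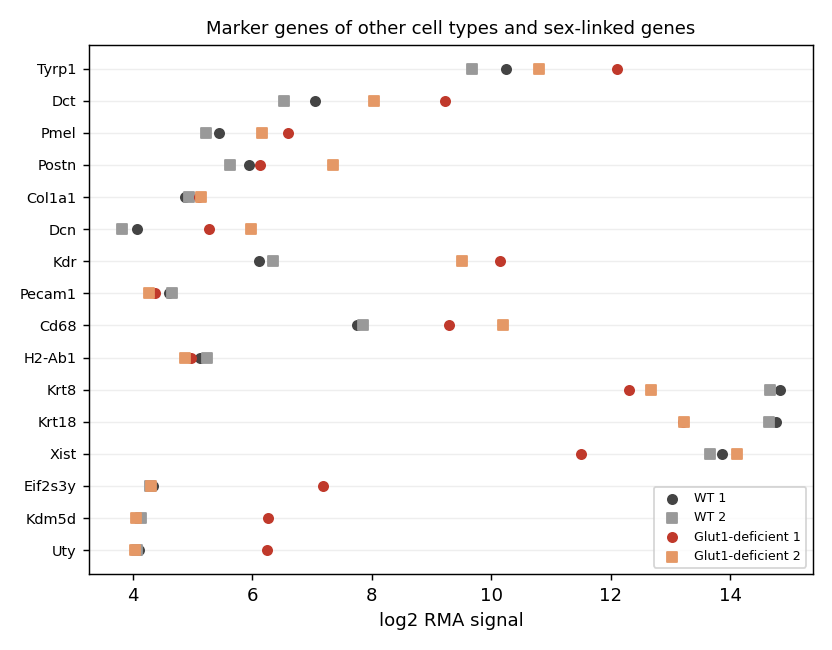
Log2 RMA signal on each of the 4 arrays (points, x axis) for markers of other cell types and sex-linked genes (y axis). Tyrp1 reached 12.11 on Glut1-deficient replicate 1, the array on which Eif2s3y, Kdm5d and Uty also stood highest.

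In the other marker lists 1 of 10 endothelial markers rose, Kdr by 3.60 (SE 0.23), with 9 not passing (1 higher adjusted over the list alone; camera adjusted p = 0.563). In leukocyte markers 1 of 17 rose, Cd68 by 1.95, with 16 not passing (1 higher adjusted over the list alone; camera adjusted p = 0.707). Merkel and neural markers fell in 2 of 8 members, the simple epithelial keratin genes Krt8 by 2.25 and Krt18 by 1.48, with 6 not passing (2 lower adjusted over the list alone; camera adjusted p = 0.919; lower by fry, adjusted p = 0.0455). Lgr6, at least 3.58-fold lower with Glut1-deficient arrays at background, was the 1 of 21 hair follicle and sebocyte markers that fell, with 20 not passing (1 lower adjusted over the list alone; camera adjusted p = 0.887), and Fabp4 the 1 of 11 muscle and adipocyte markers that rose, at least 1.19-fold from background, with 10 not passing (1 higher adjusted over the list alone; camera adjusted p = 0.919). Fabp4 was lost whichever of the 4 arrays was left out (adjusted p from 0.0985 to 0.203), Cd68 without wild-type replicate 1 or 2 (0.0913 and 0.0756) and Lgr6 without Glut1-deficient replicate 1 or 2 (0.0763 and 0.0500). In these fits 1 endothelial, 0 to 1 leukocyte, 2 Merkel and neural, 0 to 1 hair follicle and 0 muscle and adipocyte markers passed. The hair follicle marker Cd34 had a log2 fold change of 2.19 (adjusted p = 0.0898), which was 3.06 and passed without Glut1-deficient replicate 1 (0.0341) and was 1.33 without replicate 2. Median, mean and test differed in sign for 5 lists. Pentose phosphate genes had a median of -0.13 and a mean of 0.09 and ranked higher, Merkel and neural markers 0.19 and -0.30 and ranked higher by camera, and EGFR ligands and receptors 0.0083 and 0.19 and ranked lower. Leukocyte markers had a median of -0.025 and a mean of 0.064, and muscle and adipocyte markers -0.017 and 0.0049, and both ranked lower.

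Sex-linked genes, singled out after their values were seen, differed between the Glut1-deficient arrays. Eif2s3y was 7.19 on replicate 1 and 4.30 on replicate 2, against 4.33 and 4.29 on the wild-type arrays. Xist was 11.50 on replicate 1 and 14.12 on replicate 2, against 13.86 and 13.66 in wild type. Of the 34 lists 15 passed in all, 11 higher and 4 lower. None passed with an estimated correlation, where 1 list had an unadjusted camera p under 0.05. That test rests on 2 residual degrees of freedom, so few lists could pass it. The basal keratinocyte list had an estimated correlation of 0.013, near the preset 0.01, yet its unadjusted camera p went from 4.16e-07 to 0.0382. By fry 12 lists passed, 9 of them among the 15 and in the same direction, and 3 outside the 15: the alarmin, Mondo target and Merkel and neural lists, all lower. The other 6 of the 15 were G2 and M phase, fatty acid oxidation, early differentiation, hypoxia, Nrf2 and melanocyte genes (fry adjusted p = 0.0612, 0.0612, 0.0707, 0.0775, 0.125 and 0.177).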

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

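All tests in this part were chosen only after the results they bear on were seen. Signal outside the comparison drew attention in 2 places. Among 35352 rows that name several genes or none, 17 were higher in the Glut1-deficient arrays and 11 lower, 6 of these 28 naming several genes and 22 none. The Bs-thr spike, a control RNA rather than mouse RNA, was 1.34 higher on the log2 scale in the Glut1-deficient arrays. The means of all the other spike rows were higher there too, by 0.019 to 0.29, against a median of -0.011 over the named rows. Such a technical difference runs along with genotype, and its effect on the comparison was not tested.

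The rise of autophagy and lysosome genes may come in part from more melanocyte RNA, since melanocyte markers ranked higher in the same arrays. A first test compared the mean rise on Glut1-deficient replicate 2 with that on replicate 1: the ratio was 0.803 (95% bootstrap interval over genes 0.667 to 0.937) for the list and 0.472 (0.371 to 0.577) for 10 markers above background, so the 2 sets moved apart between these arrays. A second test, put in its place after that result was known, rests on single arrays as well: the list lay 0.515 (0.263 to 0.801) higher on Glut1-deficient replicate 2 than on wild-type replicate 1 and the markers 0.445 (0.253 to 0.629), which decides nothing, as a shared source does not make the rises of different genes equal. Melanocyte RNA and a change within keratinocytes cannot be told apart for this list, because the intervals run over genes and leave out the spread between arrays, the Glut1-deficient side of each comparison is a single array, and no sort of the cells is given in the sources used here.

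Vim and Bgn, named after their values were seen, rose by 2.88 (SE 0.54) and 3.25, with 3.71 and 3.95 without Glut1-deficient replicate 1 and 2.04 and 2.55 without replicate 2, and could come from fibroblasts. The highest log2 fold change plus 2 SE among the fibroblast collagens Col1a1, Col1a2 and Col3a1 was 0.588 against a lower bound of 1.80 for Vim and Bgn, which was first read as excluding fibroblast RNA, with the pattern reworded from all fibroblast markers to these genes after its result was seen. This reading was withdrawn by a rule also added after the result: all 3 lay below the highest background control row on every array, where folds may be compressed, although by the floor used elsewhere only Col3a1 lay at background in both groups. Dcn rose and fibroblast markers ranked higher, so fibroblast RNA, RNA of another mesenchymal cell and a change within keratinocytes cannot be told apart. Both calls were lost without wild-type replicate 1 or 2 (adjusted p = 0.107 and 0.125 for Vim, 0.0640 and 0.0695 for Bgn), and over all alternatives the adjusted p reached 0.159 for Vim and 0.106 for Bgn.

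Male RNA on Glut1-deficient replicate 1, where the Y-linked genes stood above the other arrays, could have produced changes between the groups. Without that array 314 rows passed, of which 285 were among the 2209 and moved the same way, so male RNA does not account for those. The sex of the pooled mice stays open as a source of part of the other changes.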

How the results depend on the processing

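Of the alternatives in this part, a block with crossed numbers and a test of every row except control rows were chosen after seeing the data. Slc2a1 was lower in every alternative, with log2 fold changes from -1.35 to -1.21 when 1 array was left out, where its adjusted p passed the threshold except without Glut1-deficient replicate 1 (0.0508); it also missed it at -1.28 when every row was tested (0.0648). Testing every row except control rows kept the call of Slc2a1 (limma adjusted p = 0.0216), so more rows alone did not end it. The control rows also changed the variance moderation. Beyond these points and the smaller number of arrays, the cause was not tested. The count of changed rows ranged from 314 to 1214 without 1 array, with 210 to 729 higher and 104 to 485 lower, the lone array being assumed to vary like the other group. Fits on 3 arrays have 1 residual degree of freedom in place of 2. Their list tests kept the preset correlation of 0.01, so lists that stayed past the threshold there are no measure of the spread between arrays. Testing every row gave 74 (54 higher, 20 lower), and testing every row except control rows gave 1033 (593 higher, 440 lower). Both add rows to the adjustment, 72688 and 65956 in place of 30604, and both change the variance moderation. Its prior degrees of freedom were 2.38 with every row and 3.26 without control rows, against 3.18 in the main fit. The prior variances were 0.0195, 0.0182 and 0.0134. Only the 6732 control rows separate the 2 settings, so the number of rows alone does not account for the count of 74. An adjusted p under 0.1 gave 3896 (2113 higher, 1783 lower), and an unadjusted p under 0.05 with at least 2-fold change gave 897 (506 higher, 391 lower). With the replicate number as a block 1849 rows passed and 16 lists. Same-numbered arrays deviated in opposite directions (correlation -0.23 across rows, which are not independent), and a block with crossed numbers gave 2039 rows. Gene lists passing numbered 13 to 17 in the alternative fits and 12 with fry, 9 of them among the 15 in the same direction, and 0 by camera with an estimated correlation, where 1 list had an unadjusted p under 0.05. Of 34 lists 30 kept their direction and side of the threshold in every alternative fit in which they were tested; the exceptions were the unfolded protein response, Nrf2, tricarboxylic acid cycle and cornified envelope lists. Of 168 other named genes 59 did so in every alternative in which they were tested, and none changed direction past the threshold. With rows at or above the median mean, 5 lists and 17 of these genes were not tested. Quantile normalization and median centring put the median of all rows at 0.014 and 0.015, against -0.011. Background limits dim genes: 28 changed rows lay at background in both groups.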

Other observations

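The lists, genes and tests in this part were chosen only after the data had been seen, so each result is a hypothesis. Many lysosomal genes and known targets of the MiT/TFE transcription factors were higher: 25 of 37 rose and none fell. Beyond Gpnmb they included Mcoln3 (3.40), Hexa (3.06, a lysosomal hexosaminidase), Rragd (2.42) and Gaa (1.85, acid glucosidase). Leaving out the members noticed before the list was written, 13 of 25 rose with a median log2 fold change of 0.84, where 10000 random lists matched on signal held a mean of 3.67 changed genes and a share of 1e-04, the smallest they can give, held as many. The hypothesis that the other members were higher as a set had a camera adjusted p of 2.42e-13 over the 4 lists of this part, with adjusted p = 0.281 with an estimated correlation. Melanocytes also express several of these genes, so melanocyte RNA stays open as a source of part of these rises too. The melanocyte markers Tyrp1 and Dct had log2 fold changes of 1.49 (SE 0.46) and 1.84 (SE 0.41), which did not pass. Gpnmb (5.00, SE 0.14) and Mcoln3 (3.40, SE 0.18) rose more than these markers, while the median of 0.84 above was lower.

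Many targets of NF-kB were lower: 16 of 31 fell and none rose past the threshold. The falls included Csf2 (-3.27), Csf1 (-2.66), Tnfaip3 (-2.30) and Tnf (-2.15), all noticed before the list was written. Some members that did not pass had positive log2 fold changes, such as Ccl2 (1.39), Ptgs2 (0.42) and Nfkbia (0.25). Of the 21 members not noticed first 6 fell, and the hypothesis that they were lower as a set had a camera adjusted p of 0.00249, with adjusted p = 0.281 with an estimated correlation. Random lists held a mean of 2.81 changed genes, and a share of 0.0465 held as many. Targets of YAP and TAZ fell in 8 and rose in 2 of 25 members, Thbs1, Igfbp3 and Ccn1 among the falls, and for the 20 members not noticed first the hypothesis of a lower rank as a set did not pass its test (camera adjusted p = 0.226; adjusted p = 0.577 with an estimated correlation). Of these 20, 6 changed, against a mean of 3.27 in random lists, of which a share of 0.0947 held as many.

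Peg3, Mest (2.17), Grb10 (2.27) and Impact (1.95), all imprinted, rose, and the imprinted gene Slc38a4 fell by 2.51. The hypothesis that imprinted genes changed more often than others of like signal stays undecided. Values of the whole list had been seen before it was tested. Apart from these 5 genes, 6 of 49 changed, against a mean of 3.54 in random lists, and a share of 0.130 of random lists held as many.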
